A study of Homo sapiens with 18 samples.

How the data were processed

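Gene expression was measured by bulk RNA-seq in foregut endoderm made from human H1 embryonic stem cells, in 6 groups of 3 libraries (18 in all). Per the labels, all-trans retinoic acid was given at 2 µM for 24 h up to day 6, CHIR99021 at 2 µM with BMP4 at 50 ng/mL for 72 h up to day 9, RNA was taken with a Nucleospin kit and libraries were made with the TruSeq stranded mRNA kit. The groups were untreated day 6, day 6 with RA, untreated day 9, day 9 with RA, day 9 with CHIR99021 and BMP4, and day 9 with RA then CHIR99021 and BMP4. Groups and replicate numbers came from the sample labels, and no sample was left out of the main comparisons.

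The authors deposited a table of raw counts per gene and a table of TPM (transcripts per 1000000), each with 1 column per library and 35025 genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.9 to GRCh38. The step that assigned reads to genes, the annotation and the strand setting are not given in the sources used here, so genes that overlap another gene or lie antisense to one are uncertain. The deposited TPM values were checked against the counts: over 7718 genes with more than 100 counts in every library, each TPM was the count divided by 1 length per gene and 1 factor per library, to within 1.33e-09 in log2. 36 genes without a symbol held 0.001% of all counts. Gene starts in the count table equalled the RefSeq start minus 1 for 17764 of 25696 genes found in both.

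Totals per library, in M counts (M, 1000000), were 7.53, 6.33 and 9.23 (untreated day 6), 8.88, 12.11 and 6.95 (day 6 RA), 25.37, 5.89 and 5.79 (untreated day 9), 6.73, 10.75 and 9.99 (day 9 RA), 13.68, 8.71 and 18.73 (CHIR99021 and BMP4), and 19.69, 9.43 and 6.75 (RA then CHIR99021 and BMP4). Replicates varied more than counting alone gives, with a chi-square per gene of 2.17 to 10.65 for genes with at least 20 summed counts. The common dispersion was 0.00724 and the median biological coefficient of variation 8.5%. Mitochondrial protein-coding genes held 4.18% to 6.73% and the top 10 genes 6.68% to 8.50% of counts by group.

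Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10) numbered 15531. Libraries were scaled by trimmed mean of M-values, 1 quasi-likelihood fit with robust dispersion held all 18 libraries with 1 mean per group, and p values were adjusted by Benjamini-Hochberg over the tested genes. A gene with adjusted p below 0.05 was called, and called genes with a fold of at least 2 were also counted. There were 6 comparisons of 3 against 3 libraries and 2 interactions. The first interaction set the response to RA with CHIR99021 and BMP4 against that without, and the second the response at day 9 against that at day 6. Where a group had no reads, the fold was given as a lower bound with the group set to 3 counts, and where it had 1 to 3 counts, as a ratio with a 95% counting interval.

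Named genes followed a rule set before the data were examined. It took the 6 largest rises and 6 largest falls per comparison (4 and 4 per interaction) among called genes with at least 5 CPM in the higher group and libraries that did not overlap, 38 genes fixed for their known roles, and up to 4 called members per described list. Some genes that the rule names are not reported here. Genes with clone, antisense or pseudogene names were passed over. IGF2 and the globin genes lay outside the rule and were chosen after their values were seen. 29 gene lists with 491 of 509 entries in the table were fixed from general knowledge of foregut patterning, signalling, stress and other cell types. Lists with at least 5 tested members (27 per comparison, 216 tests) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The tests were repeated with an estimated correlation and with fry, and adjusted over the lists of a comparison. 74 list tests passed with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0764.

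The labels state no pairing of replicates, so no block was used in the main comparisons. The method was tested on simulated data of 15531 genes: 1.5-fold, 2-fold and 4-fold changes were recovered at 64.2%, 80.6% and 97% for RA before CHIR99021 and BMP4, 67.2%, 86.6% and 95.5% for CHIR99021 and BMP4 after RA, and 43.3%, 71.6% and 92.4% for their interaction, with 3.5% to 6.4% false calls. Each simulation changed only 67, 67 and 66 genes at these folds, up and down, in a single group and with no read-kind difference. The real comparisons called 6654 to 10105 genes, so the simulated rates may not hold for them. Unchanged simulated groups gave 0 calls, and 3.5% of 200 random lists had a camera p below 0.05. Simulated genes varied independently of each other, so this share is no check of the preset correlation. In the real libraries the estimated correlation was 0.754 for mitochondrially encoded genes.

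Alternatives planned with that rule were RLE and upper quartile factors, DESeq2 1.42.0, all genes with a read, 1 CPM in 3 libraries, only the groups compared, a replicate block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library in turn. Chosen after seeing the data were protein-coding genes alone (also for the change shared between comparisons), those without a pseudogene named after them, untreated day 6 replicates 1 and 3 left out, and a read-kind covariate. The covariate was the share of reads of the treated kind in each library, from genes at least 10-fold apart between sets with at least 5 CPM (untreated) or 2 CPM (treated). The limits were chosen after the pattern was seen. All treated libraries shared a covariate value, and untreated libraries other than day 6 replicates 1 and 3 shared a lower one. The effect of the covariate was therefore estimated within the untreated day 6 libraries alone and carried over to the other groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.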

Results

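The deposited tables held 18 bulk RNA-seq libraries from 6 groups of 3: untreated foregut endoderm at day 6 and day 9, endoderm given retinoic acid (RA) from day 5 to day 6 and taken at day 6 or day 9, endoderm given CHIR99021 and BMP4 from day 6 to day 9, and endoderm given both in turn. HOXB1, a direct RA target, had no reads in the 3 untreated day 6 libraries and stood at 140 ± 32.9 CPM at day 6 after RA. NKX2-1, an early marker of the respiratory domain, was highest after RA followed by CHIR99021 and BMP4 (79.3 ± 8.66 CPM), and MYH6, a cardiac myosin, was highest at day 9 after RA alone (723 ± 171 CPM). Levels are counts per 1000000 (CPM) after library scaling, and ± is the standard deviation, n = 3. Nothing in the labels says that replicates were separate cultures, so p values measure the spread between these libraries only, and fold bounds and counting intervals cover counting error only. Totals ran from 5.79 to 25.37 M counts (M, 1000000), and 15531 genes were tested. A gene was called where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p below 0.05. Rises and falls in a gene list are calls over all tested genes, and counts adjusted over the list alone are given where they differ. The camera p uses a preset correlation and the p after it, marked estimated, an estimated one.

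**Figure D1:**
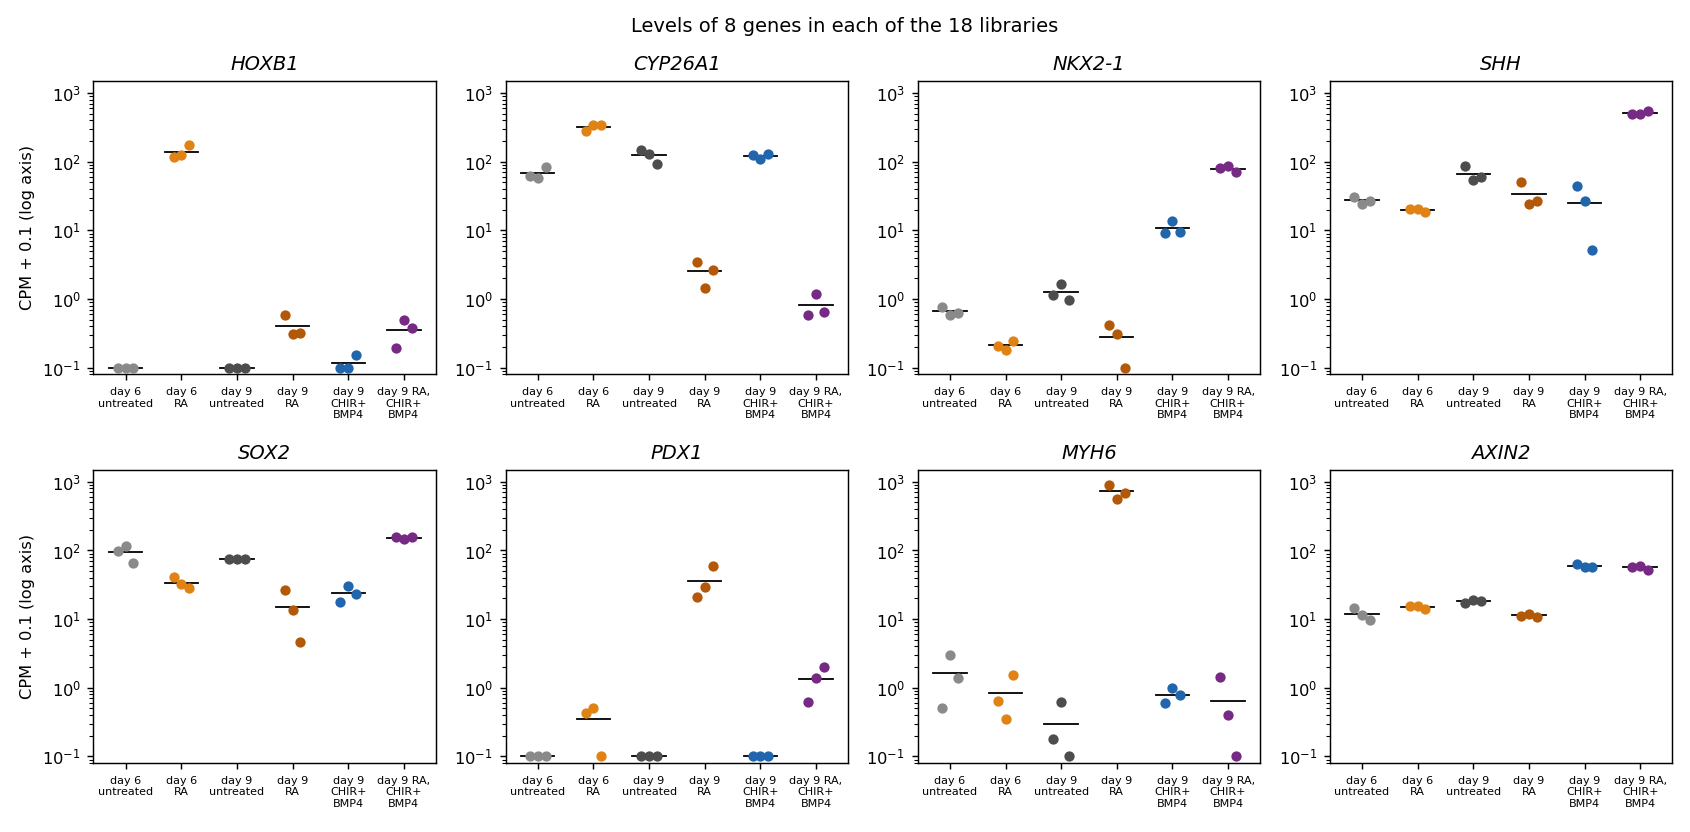
Levels of 8 genes in each library (CPM + 0.1, log axis, line at the group mean) by group. NKX2-1 and SHH were highest after RA then CHIR99021 and BMP4 (79.3 and 516 CPM), and PDX1 and MYH6 at day 9 after RA alone (36.2 and 723 CPM).

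The 6 groups lay apart on the first 3 principal components of log2 CPM, which held 31.7%, 23.1% and 20.4% of the variance. Another difference followed the groups. Of 60 genes at least 10-fold apart between untreated and treated libraries, 56 (93.3%) were pseudogenes, against 3.63% of 13718 genes of at least 2 CPM. 29 of them were higher in the untreated and 31 in the treated libraries, and untreated day 6 replicates 1 and 3, left out of this choice, lay between (treated-set share 26.5% and 43.4%). POTEE, PGAM1 and PGAM4, which share sequence with near copies, stay uncertain for this reason. POTEE and PGAM4 were themselves among the 60 genes, from which the read-kind covariate was made. Untreated and treated groups differed in this read kind in 3 comparisons and 1 interaction below. Both mixed libraries belonged to untreated day 6, so day 9 against day 6 without treatment and RA by day carried part of it too. The number of calls with the read kind as a covariate is given for all of these, with covariate values for some genes only. Other fold changes and p values come from the fit without that covariate. That covariate varied within a group only among the untreated day 6 libraries, so which calls stayed or ended with it rests on these. RA before CHIR99021 and BMP4, and CHIR99021 and BMP4 after RA, were compared within one kind.

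**Figure D2:**
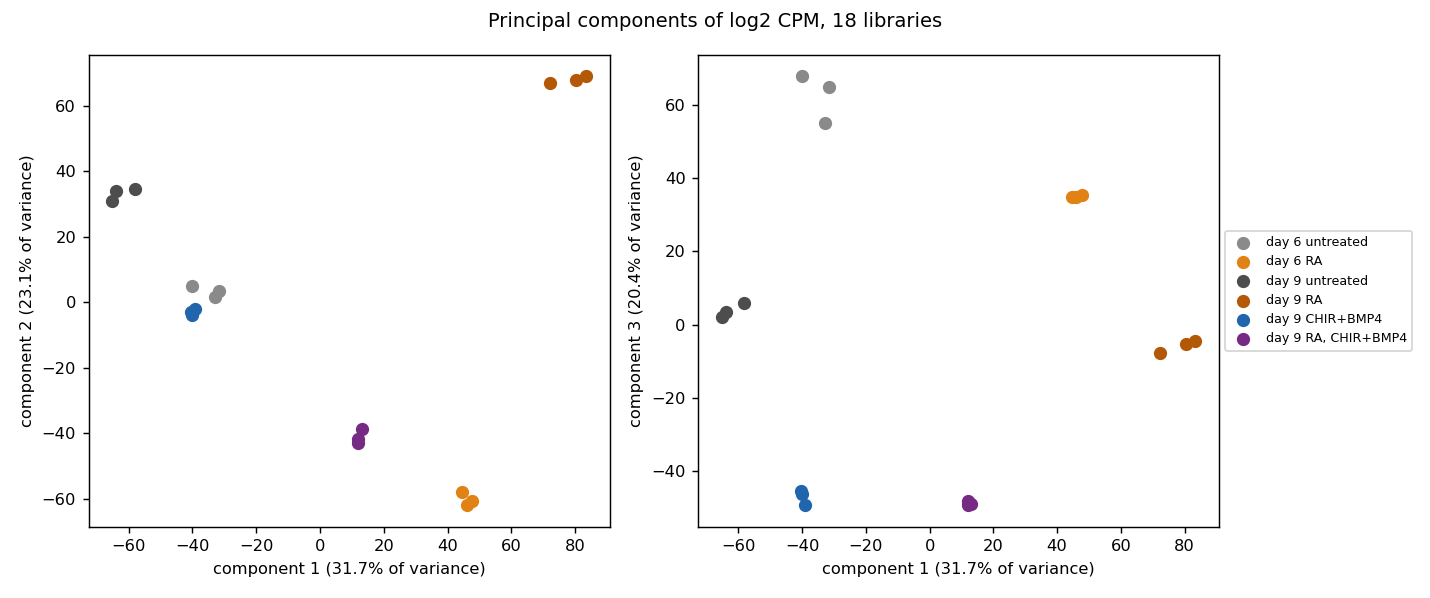
Components 1 and 2 (left) and 1 and 3 (right) of log2 CPM for the 18 libraries, with the share of variance on each axis. Component 1 (31.7%) ran from untreated day 9 to day 9 after RA.

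At day 6, after 24 h of RA, HOXB1 and HOTAIRM1 were higher and OTX2, PAX1 and PAX9 lower than in untreated cells. HOXB1 went from no reads to 140 ± 32.9 CPM (at least 1080-fold, adjusted p = 1.4e-13). HOTAIRM1, a noncoding transcript of the HOXA cluster, went from 1 count over 3 libraries to 347 ± 12.9 CPM, a ratio of 8010 (counting interval 1440 to 316000). OTX2, a regulator of anterior identity, fell 10.4-fold (482 ± 22.1 to 46.3 ± 0.519 CPM). PAX1 and PAX9, markers of the pharyngeal pouches, fell 524-fold (118 ± 28.5 to 0.223 ± 0.213 CPM) and 79.9-fold (15 ± 2.89 to 0.155 ± 0.135 CPM).

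Among the 3' HOX genes, 7 of 7 tested rose and 0 fell, with a median log2 fold change of 7.93 (4.73 with absent groups set to the bound, camera adjusted p = 2.6e-07, estimated 0.0862). These 7 of 15 listed genes passed the low-count filter. Genes absent from untreated cells could pass it only through reads in treated groups. The filter thus favoured a rise, and the share that rose is not independent of it. HOXB2 rose from 0.24 ± 0.212 to 55.9 ± 2.15 CPM and HOXA3 from no reads to 2.86 ± 1.07 CPM (at least 22-fold). Among the retinoid pathway genes, 10 of 17 rose and 3 fell (camera adjusted p = 0.00893, estimated 0.0925). CYP26A1 and DHRS3, which lower RA levels, rose 4.68-fold (68.2 ± 14.6 to 321 ± 37.6 CPM) and 14.5-fold (14.2 ± 1.56 to 205 ± 3.18 CPM), RARB rose 2.36-fold and CYP26B1 45.4-fold (0.258 ± 0.107 to 12.4 ± 2.75 CPM). CYP26C1, of the same enzyme family, fell 360-fold (181 ± 102 to 0.509 ± 0.0871 CPM, adjusted p = 8.3e-08).

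Among the anterior and pharyngeal genes, 2 of 21 rose and 16 fell (2 and 18 over the list alone) (camera adjusted p = 2.6e-07, estimated 0.0925). TBX1 fell 4.59-fold (15.5 ± 4.53 to 3.64 ± 1.85 CPM), ISL1 5.68-fold (80 ± 23.7 to 14.3 ± 2.16 CPM) and NKX2-5 24.4-fold (6.98 ± 2.87 to 0.316 ± 0.203 CPM). DMBX1, PCDH8 and PODN were among the largest falls (147 ± 54.7 to 0.213 ± 0.0908 CPM, 65.1 ± 13.2 to 0.129 ± 0.123 CPM and 64.4 ± 12.8 to 0.232 ± 0.132 CPM). Among the liver and pancreas genes, 14 of 20 rose and 1 fell (camera adjusted p = 9.2e-05, estimated 0.0925): HNF4A rose 9.7-fold (2.61 ± 0.918 to 24.7 ± 6.44 CPM), ONECUT2 from 0.938 ± 0.69 to 169 ± 21.6 CPM and APOA2 from 3.82 ± 0.0658 to 208 ± 21.7 CPM, while RFX6 and MNX1 went from 3 counts each to 43 ± 2.62 and 39.4 ± 9.07 CPM. PDX1 was at 0.247 ± 0.217 CPM and did not pass (adjusted p = 0.315). Among the pan-endoderm genes, 13 of 16 rose and 2 fell (camera adjusted p = 4.7e-04, estimated 0.0925). GATA6 rose 8.91-fold (22.3 ± 2.16 to 198 ± 20.5 CPM), GATA4 7.69-fold and FOXA2 2.55-fold (92 ± 2.87 to 235 ± 7.76 CPM).

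Among BMP targets, 1 of 19 rose and 11 fell (camera adjusted p = 4.7e-04, estimated 0.386). BMP4 itself fell 6.02-fold (714 ± 28.9 to 119 ± 5.15 CPM) and ID1 3.7-fold (105 ± 32.4 to 28.8 ± 8.05 CPM). Among FGF targets, 2 of 15 rose and 10 fell (camera adjusted p = 0.00779, estimated 0.208). SPRY1 fell from 121 ± 15.5 to 12.2 ± 1.47 CPM, ETV5 fell from 51.2 ± 4.95 to 8.95 ± 0.999 CPM and DUSP4 rose from 35.5 ± 6.91 to 188 ± 20.3 CPM. Among Hedgehog pathway genes, 1 of 16 rose and 9 fell (camera adjusted p = 0.0317, estimated 0.0925). GLI1 fell 2.28-fold, IHH rose from 3.95 ± 1.66 to 242 ± 17.8 CPM, and SHH was at 27.2 ± 2.83 to 19.7 ± 1.16 CPM (adjusted p = 0.547). SOX2 fell 2.74-fold (93.6 ± 26.2 to 33.8 ± 6.86 CPM), and TP63, a marker of basal and oesophageal epithelium, fell 11.9-fold (10.8 ± 2.78 to 0.857 ± 0.138 CPM). IGF2, which was chosen after its level was seen, rose from 21 ± 8.25 to 3119 ± 363 CPM. Among mesenchyme markers, 1 of 17 rose and 9 fell (camera adjusted p = 0.00893, estimated 0.449), and among endothelial and blood genes 0 of 13 rose and 4 fell (0 and 3 over the list alone) (camera adjusted p = 0.047, estimated 0.617). Among integrated stress genes, 0 of 14 rose and 8 fell (0 and 9 over the list alone) (camera adjusted p = 0.00425, estimated 0.465). DDIT3 fell 2.27-fold (15.6 ± 2 to 6.86 ± 0.282 CPM) and XBP1 2.04-fold (169 ± 25.7 to 82.7 ± 6.42 CPM). Among cell cycle genes, 0 of 20 rose and 8 fell (camera adjusted p = 0.00996, estimated 0.465). MCM6 fell 1.57-fold (367 ± 13 to 234 ± 14 CPM). HBB had 501, 44 and 350 counts in the untreated day 6 libraries and 9, 0 and 0 after RA.

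In the edgeR quasi-likelihood test 7571 of 15531 genes were called at day 6 (3929 up, 3642 down), of which 1296 rose and 1213 fell at least 2-fold. On TPM values 6254 rose and 2085 fell (75% against 51.9% up), with a median shift of 0.196 in log2, and with upper quartile factors 3846 rose and 3760 fell. With the read kind as a covariate 1106 genes were called, and simulated 4-fold changes were recovered at 50% in place of 93.9%, with 11.4% false calls in place of 5.8%. POTEE, DMBX1, PAX1, PCDH8, CYP26C1, PODN, DHRS3, RARB, TBX1, PAX9, OTX2, ID1 and BMP4 were among the 14 of 33 calls among the largest changes and fixed genes that stayed, and these 33 kept their direction. POTEE was itself among the genes that defined the covariate. With list members included, 40 of 120 named calls stayed and 118 kept their direction. HOXB1 has no reads in untreated day 6 libraries and did not pass in that fit.

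At day 9, 3 days after RA was removed, MYH6, CDX2, PDX1 and SPINK1 stood high. MYH6 went from 0.197 ± 0.275 to 723 ± 171 CPM (4840-fold, adjusted p = 4.4e-11). CDX2, a regulator of the intestine, and PDX1, of pancreas and duodenum, went from no reads to 36.5 ± 20.4 and 36.2 ± 20 CPM (at least 445-fold and 441-fold, adjusted p = 1.4e-07 and 2.9e-05). SPINK1, a trypsin inhibitor of the pancreas, went from no reads to 87.7 ± 24.8 CPM (at least 1070-fold). CYP26A1, higher after RA at day 6, was 54.4-fold lower than in untreated cells at day 9 (125 ± 28.3 to 2.43 ± 1.01 CPM, adjusted p = 1.2e-10).

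Among liver and pancreas genes, 17 of 20 rose and 0 fell (camera adjusted p = 7.5e-08, estimated 0.0933), with a median log2 fold change of 5.09 (5.07 with the bound). HNF4A rose 78.3-fold (1.04 ± 0.351 to 81.9 ± 20.9 CPM), HHEX 7.14-fold (34.8 ± 3.62 to 245 ± 42.4 CPM), ONECUT1 from 0.164 ± 0.161 to 94.5 ± 37.1 CPM and ONECUT2 from 1.85 ± 0.345 to 499 ± 333 CPM. Among mid and hindgut genes, 4 of 5 rose and 1 fell (camera adjusted p = 0.0351, estimated 0.138), with VIL1, of the brush border, up from 5.09 ± 2.35 to 121 ± 39.9 CPM. Among pan-endoderm genes, 13 of 16 rose and 2 fell (camera adjusted p = 8.6e-04, estimated 0.138). FOXA1 rose 7.34-fold (35.4 ± 1.07 to 260 ± 15.5 CPM), FOXA2 3-fold (34.1 ± 2.96 to 104 ± 12.8 CPM) and GATA6 19.8-fold.

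Among cardiac and splanchnic genes, 10 of 14 rose and 2 fell (11 and 2 over the list alone) (camera adjusted p = 0.0124, estimated 0.186). MYBPC3 and SMYD1, of the sarcomere, went from no reads to 45.8 ± 10.7 and 33.8 ± 6.99 CPM (at least 558-fold and 411-fold), MYL7 rose from 8.74 ± 3.65 to 553 ± 74 CPM, and TCF21 fell from 5.7 ± 2.75 to 0.144 ± 0.163 CPM. Among mesenchyme markers, 11 of 17 rose and 1 fell (12 and 1 over the list alone) (camera adjusted p = 0.0118, estimated 0.439). COL1A1 rose 8.26-fold (196 ± 93.4 to 1606 ± 290 CPM) and POSTN 8.46-fold (11.6 ± 3.03 to 105 ± 59.9 CPM). Among cell cycle genes, 0 of 20 rose and 19 fell (camera adjusted p = 2.5e-06, estimated 0.179). MCM2 fell from 279 ± 17.6 to 98.4 ± 9.27 CPM and MCM5 from 136 ± 6.46 to 56.9 ± 4.18 CPM. Among mitochondrially encoded genes, 0 of 13 rose and 8 fell (camera adjusted p = 0.0204, estimated 0.605). COX1 fell from 20599 ± 1754 to 11758 ± 786 CPM.

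The 3' HOX genes that passed the filter stayed up (7 of 7 rose and 0 fell, camera adjusted p = 5.3e-04, estimated 0.138). HOXB2 was at 16.8 ± 7.92 CPM against 55.9 ± 2.15 at day 6. Among anterior and pharyngeal genes, 3 of 21 rose and 17 fell (camera adjusted p = 5.3e-04, estimated 0.276). FOXE1, a thyroid and pharyngeal regulator, fell 16.9-fold (295 ± 15.5 to 19 ± 19.4 CPM), VGLL2 200-fold (82.7 ± 23.5 to 0.429 ± 0.184 CPM) and TBX1 10.2-fold. PAX9, which was lower after RA at day 6, had a higher mean after RA than without it at day 9. Among Hedgehog pathway genes, 3 of 16 rose and 10 fell (camera adjusted p = 0.0359, estimated 0.138), with PTCH1 and GLI1, both targets of the pathway, down 4.78-fold (475 ± 51.6 to 100 ± 27.1 CPM) and 9.59-fold (46.5 ± 1.91 to 5.01 ± 1.94 CPM), while SHH was at 67.2 ± 17.7 to 33.8 ± 14.5 CPM (adjusted p = 0.0845). NKX2-1 fell 6.43-fold (1.15 ± 0.345 to 0.177 ± 0.163 CPM), SOX2 5.32-fold (74.7 ± 0.752 to 14.9 ± 11.1 CPM) and TP63 38.8-fold (60.2 ± 4.7 to 1.74 ± 1.57 CPM). MUC15 went from 5.56 ± 1.08 CPM to no reads, and CYP26C1 fell 79.4-fold (122 ± 22.7 to 1.67 ± 1.09 CPM). HBB had 754, 42 and 2071 counts in the untreated day 9 libraries and 0, 0 and 142 after RA.

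By the edgeR quasi-likelihood test, 10105 genes were called at day 9 (5054 up, 5051 down), of which 1939 rose and 1852 fell at least 2-fold. On TPM values 7722 rose and 2776 fell, with a median shift of 0.322 in log2, and with upper quartile factors 4394 rose and 5864 fell. With the read kind as a covariate 1272 genes were called, and simulated 4-fold changes were recovered at 31.8% in place of 92.4%, with 8.7% false calls in place of 5.7%. At day 9 the covariate has the same split as untreated against treated, so its effect there is carried over from untreated day 6. MYH6, MYBPC3, SMYD1, POTEE, MUC15, VGLL2, ANKRD63, CYP26A1, CYP26C1, GLI1, TBX1, BMP4 and TP63 were among the 14 of 38 calls among the largest changes and fixed genes that stayed, and 36 kept their direction. Of these, POTEE helped to define the covariate. With list members included, 39 of 136 named calls stayed and 127 kept their direction. LEF1 and ID1, both fixed genes, were among those that changed sign. Their main log2 fold changes were -1.53 and 0.81. With the covariate they were 2.08 and -0.98 and did not pass (edgeR adjusted p = 0.284 and 0.417).

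**Figure D3:**
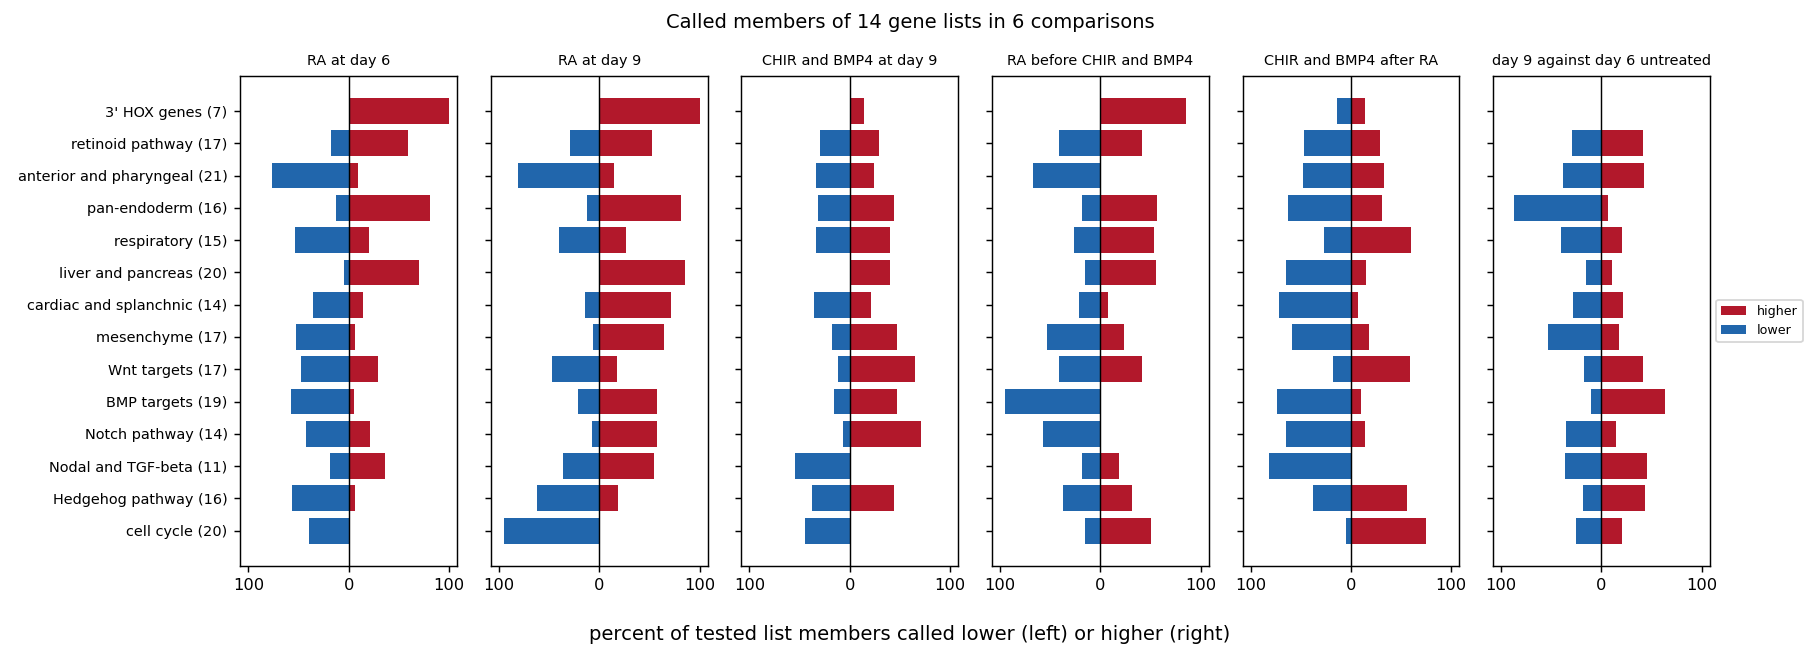
Percent of the tested members of 14 gene lists called lower (left) or higher (right) in 6 comparisons, with the number tested in brackets. After RA the 7 3' HOX genes that passed the low-count filter were higher at day 6 and at day 9. Where RA came before CHIR99021 and BMP4, 18 of 19 BMP targets were lower.

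After CHIR99021 and BMP4 without RA, the Wnt targets LGR5, NKD1 and AXIN2 and the early respiratory marker NKX2-1 were higher than in untreated day 9 cells. LGR5, NKD1 and AXIN2 rose 9.84-fold (4.18 ± 1.79 to 48.4 ± 16 CPM), 6.27-fold (16.6 ± 0.947 to 103 ± 10.2 CPM) and 3.3-fold (18 ± 0.813 to 58.8 ± 3.82 CPM, adjusted p = 5.0e-12). NKX2-1 rose 9.38-fold (1.15 ± 0.345 to 10.7 ± 2.58 CPM, adjusted p = 8.7e-11), and IRX3, expressed in early lung epithelium, from 1.27 ± 1.08 to 27.7 ± 1.29 CPM. HMX3 and RORB, transcription factors of sensory and neural tissue, went from 0.421 ± 0.261 to 39.7 ± 7.67 CPM and 0.154 ± 0.173 to 13.8 ± 2.11 CPM. CER1, an antagonist of Nodal, BMP and Wnt, fell 33.2-fold (47.2 ± 13.9 to 1.48 ± 0.468 CPM).

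Among Wnt targets, 11 of 17 rose and 2 fell (12 and 2 over the list alone) (camera adjusted p = 0.00261, estimated 0.266). LEF1 rose 4.82-fold (8.13 ± 1.06 to 37.7 ± 2.73 CPM) and NOTUM from 2 ± 0.705 to 12 ± 2.03 CPM. Among BMP targets, 9 of 19 rose and 3 fell (camera adjusted p = 0.0216, estimated 0.761). MSX1 rose from 0.82 ± 0.432 to 12.3 ± 1.93 CPM and HEY1 from 6.79 ± 3.07 to 25.4 ± 3.76 CPM. The BMP4 transcript itself fell 2.66-fold (190 ± 21.9 to 72.1 ± 14 CPM). MSX2 rose 2.46-fold (24.7 ± 10.2 to 65 ± 16 CPM), with a log2 fold change of 1.30 that became -4.33 with the read-kind covariate (adjusted p = 0.588). Among Notch pathway genes, 10 of 14 rose and 1 fell (camera adjusted p = 0.00406, estimated 0.266). DLL1 rose 11-fold (7.17 ± 1.58 to 84.8 ± 26.8 CPM) and JAG1 4.9-fold (88 ± 23 to 428 ± 47.2 CPM). Among Nodal and TGF-beta genes, 0 of 11 rose and 6 fell (camera adjusted p = 0.00406, estimated 0.101).

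Respiratory genes went both ways, as 6 of 15 rose and 5 fell (camera adjusted p = 0.662, estimated 0.854). IRX5 rose from 2.42 ± 0.78 to 14.5 ± 1.12 CPM and BMP4 was among those that fell. Among liver and pancreas genes, 8 of 20 rose and 0 fell (camera adjusted p = 0.0065, estimated 0.387). HNF4A rose 4.27-fold (1.04 ± 0.351 to 4.67 ± 1.29 CPM), APOA2 from 0.468 ± 0.35 to 4.07 ± 1.39 CPM and APOA1 from 6.68 ± 3.24 to 42.4 ± 7.24 CPM. Among anterior and pharyngeal genes, 5 of 21 rose and 7 fell (6 and 7 over the list alone) (camera adjusted p = 0.799, estimated 0.916). PAX1 rose 23.7-fold (15.2 ± 3.08 to 362 ± 28.3 CPM), FOXE1 fell 16.5-fold (295 ± 15.5 to 19.1 ± 11.5 CPM) and OTX2 rose 1.71-fold (188 ± 33.3 to 324 ± 30.4 CPM). SOX2 fell 3.22-fold (74.7 ± 0.752 to 23.6 ± 6.28 CPM, log2 -1.69) and CYP26C1 rose 4.99-fold (122 ± 22.7 to 615 ± 99.7 CPM, log2 2.32), and with the covariate these became 0.14 and -0.15 (adjusted p = 0.99 and 0.982). GLI1 fell 3.42-fold (46.5 ± 1.91 to 14.2 ± 6.36 CPM), RARB 3.68-fold (33.3 ± 4.74 to 8.74 ± 0.536 CPM) and DHRS3 2.94-fold. Among integrated stress genes, 0 of 14 rose and 10 fell (0 and 11 over the list alone) (camera adjusted p = 0.00406, estimated 0.761). ATF3 fell from 31.2 ± 7.93 to 10.1 ± 1.17 CPM. Among cell cycle genes, 0 of 20 rose and 9 fell (camera adjusted p = 0.0175, estimated 0.761). MKI67 fell from 574 ± 23.1 to 382 ± 16.7 CPM. Among mitochondrially encoded genes, 0 of 13 rose and 8 fell (camera adjusted p = 0.0175, estimated 0.761), and among mid and hindgut genes 2 of 5 rose and 0 fell (camera adjusted p = 0.043, estimated 0.266). HBB had 0, 81 and 0 counts after CHIR99021 and BMP4 and 0, 96 and 0 after RA then these. Ribosomal-protein genes held 3.93% of counts against 2.06% in untreated day 9 libraries. These groups also differed in read kind, and pseudogenes held 2.61% of counts against 4.02%. How much of the ribosomal-protein difference came from reads assigned differently between gene copies was not tested. Within the treated read kind, ribosomal-protein genes held 3.13% after RA then CHIR99021 and BMP4 and 1.40% at day 9 after RA.

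In the edgeR quasi-likelihood test 6654 genes were called (3268 up, 3386 down), of which 896 rose and 965 fell at least 2-fold. On TPM values 6351 rose and 1588 fell (80% against 49.1% up), with a median shift of 0.235 in log2, and with upper quartile factors 3376 rose and 3304 fell. With the read kind as a covariate 146 genes were called, and simulated 4-fold changes were recovered at 36.4% in place of 98.5%, with 7.4% false calls in place of 3.6%. FAM135B, POTEE, PGAM4 and LEF1 were the 4 of 34 calls among the largest changes and fixed genes that stayed, and 31 kept their direction (14 and 112 of 122 with list members included). POTEE and PGAM4 were among the genes that defined the covariate, so that their calls stayed says nothing about an effect of treatment.

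Among cells given CHIR99021 and BMP4, those with earlier RA had more NKX2-1, SHH and SOX2 and less TLX1. NKX2-1 rose 7.62-fold (10.7 ± 2.58 to 79.3 ± 8.66 CPM, adjusted p = 8.3e-14). SHH, the Hedgehog ligand of the ventral foregut, rose 21-fold (25.4 ± 19.6 to 516 ± 37 CPM, adjusted p = 1.7e-05), and FOXA2, which lies upstream of it, 9.5-fold (18.9 ± 7.99 to 171 ± 3.13 CPM). CPM, a surface carboxypeptidase of early lung progenitors, rose 39-fold (2.74 ± 1.81 to 93.6 ± 17.3 CPM). TLX1, a homeobox gene, went from 57.1 ± 7.94 CPM to 1 count over 3 libraries, a ratio of 2120 (counting interval 379 to 83600).

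Among respiratory genes, 8 of 15 rose and 4 fell (camera adjusted p = 0.0686, estimated 0.485). FOXP1 rose from 21.8 ± 0.869 to 102 ± 7.28 CPM, SFTA3 from 1.42 ± 0.804 to 4.75 ± 0.439 CPM, and BMP4 fell 1.89-fold (72.1 ± 14 to 37.6 ± 4.87 CPM). Among pan-endoderm genes, 9 of 16 rose and 3 fell (camera adjusted p = 0.00148, estimated 0.158). FOXA1 rose 7.58-fold (29.5 ± 2.73 to 224 ± 5.5 CPM), GATA6 8.66-fold (8.39 ± 1.59 to 71.6 ± 3.94 CPM) and SOX17 3.13-fold (4.91 ± 0.807 to 15.3 ± 0.845 CPM). Among liver and pancreas genes, 11 of 20 rose and 3 fell (14 and 3 over the list alone) (camera adjusted p = 0.0013, estimated 0.172). HNF4A rose 3.57-fold (4.67 ± 1.29 to 16.3 ± 2.11 CPM), RFX6 from 0.779 ± 0.16 to 32.3 ± 2.07 CPM and SERPINA1 from 0.115 ± 0.0927 to 5.65 ± 0.506 CPM, while HHEX fell 2.63-fold (43.5 ± 18.6 to 16.4 ± 2.02 CPM). SOX2 rose 6.6-fold (23.6 ± 6.28 to 153 ± 6.05 CPM), KRT4 194-fold (0.0888 ± 0.08 to 20.7 ± 1.35 CPM) and NTN1, a secreted guidance protein, 55.7-fold (1.51 ± 0.401 to 88.6 ± 6.98 CPM).

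Among BMP targets, 0 of 19 rose and 18 fell (camera adjusted p = 1.3e-09, estimated 0.147). MSX2 fell 6.74-fold (65 ± 16 to 9.66 ± 1.72 CPM), GATA3 9.24-fold (92.6 ± 7.01 to 10.1 ± 0.27 CPM) and ID1 2.35-fold (233 ± 32.4 to 99.2 ± 11.6 CPM). Among anterior and pharyngeal genes, 0 of 21 rose and 14 fell (0 and 15 over the list alone) (camera adjusted p = 3.5e-07, estimated 0.147). TBX1 fell 45.3-fold (9.86 ± 1.7 to 0.188 ± 0.163 CPM), OTX2 11-fold (324 ± 30.4 to 29.5 ± 5.54 CPM), PAX1 52.2-fold (362 ± 28.3 to 7.02 ± 0.514 CPM) and NKX2-5 308-fold (44.1 ± 7.3 to 0.15 ± 0.219 CPM). Among Notch pathway genes, 0 of 14 rose and 8 fell (camera adjusted p = 3.1e-04, estimated 0.147). JAG1 fell 6.78-fold (428 ± 47.2 to 63 ± 2.01 CPM) and HEY2 from 18 ± 2.55 to 0.857 ± 0.372 CPM. Among endothelial and blood genes, 0 of 13 rose and 6 fell (camera adjusted p = 0.00378, estimated 0.485). LMO2 fell 38-fold (99.9 ± 5.82 to 2.59 ± 0.1 CPM). Wnt targets were mixed, as 7 of 17 rose and 7 fell (7 and 8 over the list alone) (camera adjusted p = 0.786, estimated 0.917). LEF1 fell 2.91-fold (37.7 ± 2.73 to 13.1 ± 1.36 CPM), SP5 rose 5.02-fold (2.7 ± 0.566 to 13.1 ± 1.11 CPM) and AXIN2 was at 58.8 ± 3.82 to 56.4 ± 4.2 CPM (adjusted p = 0.653).

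Among 3' HOX genes, 6 of 7 rose and 0 fell (7 and 0 over the list alone) (camera adjusted p = 7.3e-07, estimated 0.129). HOXB2 rose from 0.157 ± 0.0599 to 6.17 ± 0.973 CPM. CYP26C1 went from 615 ± 99.7 CPM to 1 count, a ratio of 22700 (counting interval 4080 to 899000), and CYP26A1 fell 182-fold (122 ± 12.2 to 0.711 ± 0.343 CPM), while DHRS3 rose 10.6-fold (7.18 ± 1.87 to 73.1 ± 3.61 CPM) and RARB 4.85-fold (8.74 ± 0.536 to 42.7 ± 1.7 CPM). Hedgehog pathway genes went both ways (5 of 16 rose and 6 fell; camera adjusted p = 0.249, estimated 0.485): GLI2 fell 12-fold (97.7 ± 13.9 to 8.41 ± 1.2 CPM) and BOC 13.4-fold (78 ± 18 to 5.85 ± 0.153 CPM), while PTCH1 and GLI1 were higher, at log2 fold changes of 0.77 and 0.79 (adjusted p = 0.0225 and 0.0246), and did not pass without replicate 1 or 3 of CHIR99021 and BMP4 or with only the groups compared (adjusted p = 0.134 and 0.114). By the edgeR quasi-likelihood test, 6729 genes were called (3292 up, 3437 down), of which 716 rose and 1148 fell at least 2-fold. On TPM values 3833 rose and 2301 fell, and with upper quartile factors 3111 rose and 3600 fell. With the covariate all 122 named calls stayed, list members included. Both groups had the same covariate value, so that fit could not move these differences and is no check of them.

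Among cells given RA, those then given CHIR99021 and BMP4 had more NKX2-1, SHH and SOX2 and less MYH6, PDX1 and CDX2. NKX2-1 rose 459-fold (0.177 ± 0.163 to 79.3 ± 8.66 CPM, adjusted p = 1.7e-17), SHH 15.7-fold (33.8 ± 14.5 to 516 ± 37 CPM) and SOX2 10.9-fold (14.9 ± 11.1 to 153 ± 6.05 CPM). MYH6 fell 892-fold (723 ± 171 to 0.547 ± 0.702 CPM, adjusted p = 3.7e-11), and MYBPC3 went from 45.8 ± 10.7 CPM to no reads (at least 582-fold). PDX1 fell 34.5-fold (36.2 ± 20 to 1.25 ± 0.703 CPM) and CDX2 11.2-fold (36.5 ± 20.4 to 3.35 ± 0.933 CPM). Mid and hindgut genes went both ways, as 1 of 5 rose and 2 fell (camera adjusted p = 0.777, estimated 0.797).

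Among respiratory genes, 9 of 15 rose and 4 fell (10 and 4 over the list alone) (camera adjusted p = 0.0447, estimated 0.419). SFTA3, which lies beside NKX2-1, went from no reads to 4.75 ± 0.439 CPM (at least 39.3-fold), and IRX2 rose from 3.23 ± 1.59 to 57.1 ± 4.3 CPM and IRX3 from 3.71 ± 0.844 to 65.9 ± 5.73 CPM. Among Wnt targets, 10 of 17 rose and 3 fell (camera adjusted p = 0.0347, estimated 0.419). SP5 rose 52.1-fold (0.23 ± 0.165 to 13.1 ± 1.11 CPM), LGR5 18.9-fold (1.9 ± 0.933 to 34.6 ± 2.03 CPM), AXIN2 5.01-fold (11.3 ± 0.585 to 56.4 ± 4.2 CPM) and LEF1 4.77-fold. Hedgehog pathway genes went both ways, as 9 of 16 rose and 6 fell (camera adjusted p = 0.549, estimated 0.651). PTCH1 rose 3.54-fold (100 ± 27.1 to 351 ± 13.6 CPM) and GLI1 4.86-fold (5.01 ± 1.94 to 23.7 ± 3.01 CPM), and FOXL1 fell 16.5-fold (6.16 ± 1.22 to 0.348 ± 0.128 CPM). Among cell cycle genes, 15 of 20 rose and 1 fell (camera adjusted p = 6.3e-04, estimated 0.419). MCM2 rose from 98.4 ± 9.27 to 326 ± 4.26 CPM and PCNA from 75.5 ± 5.8 to 202 ± 14.1 CPM. NTN1, SLC1A2, EFCC1 and KCNC1 were among the largest rises (1.75 ± 0.394 to 88.6 ± 6.98 CPM, 0.353 ± 0.326 to 16 ± 1.34 CPM, 0.251 ± 0.0612 to 6.95 ± 0.567 CPM and 0.265 ± 0.224 to 7.96 ± 2 CPM).

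Among cardiac and splanchnic genes, 1 of 14 rose and 10 fell (camera adjusted p = 0.00174, estimated 0.224). MYL7 fell from 553 ± 74 to 3.44 ± 1.1 CPM and NKX2-5 from 12.5 ± 7.38 to 0.15 ± 0.219 CPM. Among liver and pancreas genes, 3 of 20 rose and 13 fell (camera adjusted p = 0.0224, estimated 0.419). HHEX fell 15.2-fold (245 ± 42.4 to 16.4 ± 2.02 CPM), HNF4A 5.14-fold (81.9 ± 20.9 to 16.3 ± 2.11 CPM) and ONECUT2 75.2-fold (499 ± 333 to 6.93 ± 2.91 CPM). Among Nodal and TGF-beta genes, 0 of 11 rose and 9 fell (camera adjusted p = 0.00202, estimated 0.0764). TGFBI fell 18.1-fold (198 ± 55 to 10.9 ± 2.19 CPM). Among BMP targets, 2 of 19 rose and 14 fell (camera adjusted p = 0.00174, estimated 0.419). ID1 fell 3.55-fold (352 ± 39.4 to 99.2 ± 11.6 CPM) and SMAD6 8.3-fold (226 ± 29.5 to 27.4 ± 1.57 CPM), in cells that had been given BMP4. Among Notch pathway genes, 2 of 14 rose and 9 fell (camera adjusted p = 0.0341, estimated 0.419). JAG1 fell 11.6-fold (729 ± 319 to 63 ± 2.01 CPM). Among integrated stress genes, 1 of 14 rose and 8 fell (camera adjusted p = 0.0447, estimated 0.651). ATF3 fell 11.8-fold (133 ± 13.1 to 11.4 ± 2.16 CPM). Among mesenchyme markers, 3 of 17 rose and 10 fell (4 and 10 over the list alone) (camera adjusted p = 0.0447, estimated 0.58). COL1A1 fell 16.1-fold (1606 ± 290 to 100 ± 8.48 CPM). Among amnion and trophoblast markers, 1 of 10 rose and 7 fell (camera adjusted p = 0.0249, estimated 0.419). CGA fell from 46.3 ± 12.7 to 0.284 ± 0.113 CPM and IGFBP3 from 592 ± 108 to 25.5 ± 3.58 CPM. IGF2, again chosen after its level was seen, fell from 1216 ± 99.1 to 36.9 ± 6.74 CPM, and DGKI 354-fold (97.7 ± 10.5 to 0.314 ± 0.205 CPM).

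TP63 rose 7.35-fold (1.74 ± 1.57 to 11.6 ± 0.939 CPM) and SOX17 6.1-fold (2.61 ± 1.08 to 15.3 ± 0.845 CPM), and PAX9 fell 17.6-fold (5.44 ± 2.43 to 0.263 ± 0.252 CPM). In the edgeR quasi-likelihood test 10004 genes were called (4987 up, 5017 down), of which 1589 rose and 2100 fell at least 2-fold. On TPM values 4797 rose and 4817 fell, and with upper quartile factors 5739 rose and 4450 fell. With the covariate 131 of 132 named calls stayed, list members included, but both groups had the same covariate value, so that fit is no check of them.

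Between day 6 and day 9 without treatment, SOX17 and FOXA2 fell and FOXE1 and TLX1 rose. SOX17, a marker of definitive endoderm, fell 7.05-fold (22.7 ± 5.08 to 3.5 ± 0.944 CPM, adjusted p = 2.6e-10) and FOXA2 2.66-fold (92 ± 2.87 to 34.1 ± 2.96 CPM). FOXE1 rose 50.9-fold (5.87 ± 1.07 to 295 ± 15.5 CPM) and TLX1 525-fold (0.301 ± 0.432 to 143 ± 12.3 CPM), while anterior and pharyngeal genes as a list went both ways (9 of 21 rose and 8 fell (9 and 10 over the list alone); camera adjusted p = 0.823, estimated 0.924). TP63 rose 5.73-fold (10.8 ± 2.78 to 60.2 ± 4.7 CPM).

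Among pan-endoderm genes, 1 of 16 rose and 14 fell (camera adjusted p = 4.6e-05, estimated 0.114). FOXA1 fell 4.51-fold (160 ± 14.3 to 35.4 ± 1.07 CPM) and GATA4 3.77-fold (27 ± 8.85 to 5.81 ± 3.09 CPM). Among pluripotency genes, 0 of 9 rose and 8 fell (camera adjusted p = 4.9e-04, estimated 0.114). POU5F1 fell 4.82-fold (3.48 ± 1.58 to 0.537 ± 0.336 CPM) and L1TD1 8.09-fold (31.6 ± 7.38 to 4.08 ± 0.813 CPM). Among neural crest and neuron genes, 1 of 11 rose and 7 fell (camera adjusted p = 0.00321, estimated 0.114). PAX6 fell from 5.35 ± 2.14 to 0.195 ± 0.0402 CPM and ELAVL4 from 4.7 ± 2.44 to 0.226 ± 0.104 CPM. Among FGF targets, 0 of 15 rose and 10 fell (1 and 10 over the list alone) (camera adjusted p = 0.0272, estimated 0.411). ETV4 fell from 29.6 ± 4.38 to 8.2 ± 1.4 CPM. Among BMP targets, 12 of 19 rose and 2 fell (camera adjusted p = 0.02, estimated 0.672). ID1 rose 1.91-fold (105 ± 32.4 to 201 ± 18.4 CPM), MSX2 6.04-fold (4.05 ± 2.88 to 24.7 ± 10.2 CPM) and GATA2 7.26-fold (1.84 ± 0.554 to 13.6 ± 1.3 CPM), while BMP4 fell 3.75-fold (714 ± 28.9 to 190 ± 21.9 CPM). Among hypoxia and glycolysis genes, 7 of 13 rose and 2 fell (8 and 2 over the list alone) (camera adjusted p = 0.046, estimated 0.672). LDHA rose 3.63-fold (186 ± 17.4 to 677 ± 70.4 CPM) and VEGFA fell 5.24-fold (979 ± 186 to 186 ± 26 CPM).

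PTCH1 rose 2.97-fold (159 ± 14.8 to 475 ± 51.6 CPM) and GLI1 2.96-fold (15.5 ± 4.05 to 46.5 ± 1.91 CPM), with SHH at 27.2 ± 2.83 to 67.2 ± 17.7 CPM (adjusted p = 0.0525). LEF1 rose 4.14-fold (2 ± 1.17 to 8.13 ± 1.06 CPM), AXIN2 1.52-fold (11.8 ± 2.24 to 18 ± 0.813 CPM), and PI15 from 0.169 ± 0.0412 to 17.6 ± 5.25 CPM. PAX9 fell 5.54-fold (15 ± 2.89 to 2.77 ± 0.246 CPM), OTX2 2.54-fold (482 ± 22.1 to 188 ± 33.3 CPM) and RARB 2.23-fold (72.4 ± 3.07 to 33.3 ± 4.74 CPM). LMX1A fell 204-fold (35.2 ± 5.36 to 0.0804 ± 0.139 CPM), NOS2 126-fold (100 ± 34.3 to 0.901 ± 0.287 CPM) and VWF, of endothelium, 64.4-fold (225 ± 39.5 to 4.04 ± 1.26 CPM). By the edgeR quasi-likelihood test, 7287 genes were called (3735 up, 3552 down), of which 1002 rose and 1116 fell at least 2-fold. On TPM values 2126 rose and 5523 fell, with a median shift of -0.177 in log2. With upper quartile factors 3807 rose and 3474 fell, and with RLE factors 3568 rose and 3750 fell. The fit without untreated day 6 replicates 1 and 3 left a single library in that group, so its calls are not counted here. With the covariate 4860 genes were called. Of 125 named calls, list members included, 99 stayed and 124 kept their direction.

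The response to CHIR99021 and BMP4 differed with and without earlier RA. The response of NKX2-1 to CHIR99021 and BMP4 was a log2 fold change of 8.84 after RA and 3.23 without it (interaction 5.61, adjusted p = 1.1e-08). SHH had 3.97 after RA, and the interaction was 5.46 (adjusted p = 3.0e-05). PTCH1, GLI1 and SOX2, which rose after RA, had interactions of 3.02, 4.05 and 5.13, and DHRS3 and RARB of 2.22 and 1.81. MYH6, HHEX and HNF4A had -11.98, -4.23 and -4.46, and LEF1, a Wnt target, had -0.01 (adjusted p = 0.978). In the edgeR quasi-likelihood test of the interaction 8300 genes were called (3966 above and 4334 below 0). On TPM values 2422 were above and 5915 below 0, with a median shift of -0.234, and with upper quartile factors 4612 were above and 3877 below 0, so the side with more genes depended on the scaling. With the read kind as a covariate 1272 genes were called, and NTN1, MYH6, TRBC2, DHRS3, RARB, GLI1 and PAX9 were the 7 of 30 calls among the largest changes and fixed genes that stayed, these 30 in the same direction. With list members included, 36 of 118 named calls stayed and 116 kept their direction.

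The response to RA also differed between day 6 and day 9. CYP26A1 went from a log2 fold change of 2.23 at day 6 to -5.76 at day 9 (interaction -7.99, adjusted p = 6.9e-11). DHRS3 went from 3.86 to 1.18 and ID1 from -1.89 to 0.81 (interactions -2.68 and 2.69). HNF4A rose more at day 9 (interaction 3.01), HHEX had an interaction of 3.10, and MYH6 had 13.40 (adjusted p = 6.6e-06). For FOXA2 no difference between the days passed (interaction 0.23, adjusted p = 0.465). By the edgeR quasi-likelihood test, 7906 genes were called (3862 above and 4044 below 0). On TPM values 4697 were above and 3233 below 0 (59.2% against 48.8% above), with a median shift of 0.127. With upper quartile factors 3365 were above and 4701 below 0, and with RLE factors 4057 and 3824. With the covariate 6608 genes were called, and 107 of 117 named calls stayed, list members included.

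GATA6, FOXA2 and the tested 3' HOX genes rose after RA at both days, and TP63 and TBX1 fell at both. Over all tested genes the log2 fold changes of RA at day 6 and day 9, which share no library, had a Pearson correlation of 0.413. Of 5384 genes called in both, 1959 were higher and 1802 lower in both and 1623 went opposite ways, where independent calls would have put 1279 and 1184 in both. Both comparisons also set one read kind against the other. Over the 14021 protein-coding genes, chosen after seeing the data, the correlation was 0.32, with 1791 genes higher, 1446 lower and 1568 opposite of 4805. HNF4A and FOXA1 rose after RA with or without CHIR99021 and BMP4. For these responses the correlation was 0.335 (0.358 over protein-coding genes), with 1557 genes higher, 1570 lower and 1599 opposite of 4726. LGR5, AXIN2 and NKX2-1 rose on CHIR99021 and BMP4 with or without RA, and there the correlation was 0.196 (0.243 over protein-coding genes), with 1452 higher, 1688 lower and 1510 opposite of 4650.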

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

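The counts of other splits were planned, and the tests of the 60 genes far apart between sets of libraries, of the mixed libraries and of the haemoglobin reads were chosen after the results were seen. Each difference listed here is one between groups, tested as an interaction. In the response to CHIR99021 and BMP4 with and without earlier RA, 8300 genes differed. NKX2-1 rose more after RA (log2 difference of 5.61). SHH, PTCH1, GLI1 and SOX2 rose after RA and had negative fold changes without it (differences of 5.46, 3.02, 4.05 and 5.13), and NTN1 and TP63 also had differences above 0 (7.69 and 3.2). Differences below 0 were found for MYH6 (-11.98), HHEX (-4.23), HNF4A (-4.46), CDX2 (-8.27) and PAX9 (-3.36). TRBC2, UTS2 and CYP26C1 had -9.65, -9.27 and -7.67. ARG1 and CDX2 had no reads at day 9 without treatment, UTS2 none after RA then CHIR99021 and BMP4, and MUC15 none at day 9 after RA, so their fitted values have no bound. With the read-kind covariate the calls of NKX2-1 (5.98, adjusted p = 0.133), SHH (5.83, adjusted p = 0.205), PTCH1 (3.60, adjusted p = 0.0788) and SOX2 (3.31, adjusted p = 0.178) ended, as did those of TP63, HHEX, HNF4A, CDX2, UTS2 and CYP26C1. Those of GLI1, NTN1, MYH6, PAX9 and TRBC2 stayed. Without RA, SOX2 went from -1.69 to 0.14 with the covariate (adjusted p = 0.99), and SHH did not pass in a fit of only the compared groups (-1.47, adjusted p = 0.237).

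Of these differences, 5 depended on single libraries. KLK10 (5.71) came to 2.46 (adjusted p = 0.902) without replicate 1 of RA then CHIR99021 and BMP4, and MUC15 (5.6) to 4.66 (adjusted p = 0.0995) without replicate 2 of that group. ARG1 (-10.71) came to -8.36 (adjusted p = 1) without replicate 1 of CHIR99021 and BMP4. AFP (-3.86) came to -2.42 (adjusted p = 0.114) without untreated day 9 replicate 1 and to -7.00 without replicate 3. SP5 (3.94) came to 0.96 (adjusted p = 0.813) without untreated day 9 replicate 1, and to 2.03 (adjusted p = 0.178) on log2(TPM + 0.1).

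In the response to RA at day 9 against day 6, 7906 genes differed. The sarcomere genes SMYD1, MYH6, MYBPC3 and UNC45B had log2 differences of 13.63, 13.4, 12.6 and 12.32. SMYD1 and MYBPC3 had no reads at day 9 without treatment and UNC45B none at day 6 after RA, so these have no bound either. PAX9, HHEX and HNF4A had 7.29, 3.1 and 3.01. The RA-degrading enzymes CYP26A1 and CYP26B1 had -7.99 and -4.63, and the mesenchyme regulators TCF21 and OSR1 -9.13 and -4.79. PI15, VWA5B1 and CDH26 had -9.45, -8.98 and -8.93: CDH26 went from 0.454 to 30.3 CPM on RA at day 6 and from 1.98 to 0.325 CPM at day 9.

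In both interactions 1 of 100 splits, the real one, gave as many genes. The splits regrouped libraries with and without RA, so every other split broke up at least part of the response to RA itself. They cannot tell an interaction from that response, and chance is not excluded as the source of these counts. The highest other splits gave 6932 and 6659 genes. These kept the libraries of one stratum whole, as did 15 and 17 of the splits (lowest 1086 and 1266), which points to the structure of the samples. Splits that kept neither whole gave at most 0. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real splits gave 7571, 10105, 6654, 6729, 10004 and 7287 genes for RA at day 6, RA at day 9, CHIR99021 and BMP4, RA before them, these after RA, and day 9 against day 6. The highest others gave 0 genes, and 1 for RA at day 9.

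The first pattern was a set of 60 genes at least 10-fold apart between treated libraries and 4 of the 6 untreated ones. Of these, 93.3% were pseudogenes, which argues for reads from near-identical copies being made or assigned differently in these sets, a candidate explanation. Treatment of the cells is argued against, since untreated day 6 replicate 1 lay 26.5% of the way to treated libraries and replicate 3 43.4%. RNA of treated cells in these libraries is argued against too, as the place of protein-coding genes had an upper limit of at most 3.6%. That limit was drawn over genes and leaves out the spread between libraries. For RA at day 9, untreated day 9 replicates 1 and 3, set against replicate 2, lay at 5.3% and 3.5% without mixing. Places this low are thus within the spread of unmixed libraries, and all are far under 26.5% and 43.4%. What made the difference stays open, since the step that assigned reads is not given in the sources used here.

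The second pattern was the large number of protein-coding genes that differed at least 2-fold between treated and untreated groups. If the read kind were the main cause, these genes would lie between the groups in the mixed libraries, and their place was at most 2.5%, against 22.9% to 41.1% for pseudogenes. Of 2047 protein-coding genes, 159 moved at least 20% toward RA in both mixed libraries and 269 away from it. Single genes that share reads with copies, such as POTEE, PGAM1 and PGAM4, stay open. An effect of treatment remains a hypothesis, since untreated and treated day 9 libraries share no read kind.

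The third pattern was haemoglobin reads, found in all 6 untreated libraries and some treated ones. HBB had 3762 counts (6.95 to 357.55 CPM) in the untreated and 328 in the treated libraries, 3 of which held 10 or more (14.21, 10.18 and 9.3 CPM). Embryonic and foetal globins had 4 counts in the untreated libraries, which argues against erythroid cells arising in the cultures. HBA1 and HBA2 had 634 counts there, 16.9% of HBB. Reads or RNA of adult blood from another sample predict such counts, but any number of them would have met this, so it decides little. They had 47 and 184 counts against 754 of HBB in untreated day 9 replicate 1, and 46 and 142 against 2071 in replicate 3. Whether treatment had a part in these reads was not tested, and where they came from stays open.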

How the results depend on the processing

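The read-kind covariate, the protein-coding sets and the fits without both mixed libraries were chosen after seeing the data, and the other alternatives were planned. Of 1458 named-gene values, 1387 kept direction and side of the threshold with DESeq2, 1446 with RLE factors, 1430 with upper quartile factors, 1416 with all genes with a read, and 1457 with 1 CPM in 3 libraries. Where fewer could be compared, 1243 of 1405 did on log2(TPM + 1), 1250 of 1405 on log2(TPM + 0.1), 1191 of 1287 with only the groups compared, 1366 of 1371 without genes that have a pseudogene named after them and 1439 of 1448 with protein-coding genes only. With the read-kind covariate 1040 of 1458 did, 380 lost the call and 14 gained it. Without both mixed libraries a single untreated day 6 library is left, so calls kept or lost in that fit are not counted here. Counts of genes within 1.5 times the main value are not listed.

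With the covariate 1106 genes were called for RA at day 6, 1272 for RA at day 9, 146 for CHIR99021 and BMP4 and 1272 for the interaction of RA with these. Simulated 2-fold changes were then recovered at 9%, 0% and 1.5% in the first 3, against 70.1%, 76.1% and 88.1% without it, which shows a loss of power, and 11.4%, 8.7% and 7.4% of calls were false, against 5.8%, 5.7% and 3.6%. Without both mixed libraries 4507 genes were called for day 9 against day 6, from fewer libraries. Over protein-coding genes only, the correlation of RA at day 6 with RA at day 9 fell from 0.413 to 0.32. That of RA at day 9 with RA before CHIR99021 and BMP4 went from 0.335 to 0.358, and that of CHIR99021 and BMP4 without and after RA from 0.196 to 0.243.

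With the covariate these log2 fold changes changed sign. None of the covariate values passed in the edgeR test (smallest adjusted p = 0.284, for LEF1), so they do not show a change in the opposite direction. RA at day 6: IFI6 -0.526 and MX1 -0.118. RA at day 9: LEF1 2.08, ID1 -0.985, KRT7 -0.862, HOXC4 -3.977, INHBA -15.111, HES4 -0.248, SFRP2 0.608, ALDH1A1 -7.082 and FGF20 0.135. CHIR99021 and BMP4: CYP26C1 -0.152, SOX2 0.144, MSX2 -4.335, RUNX1 1.954, HOXC4 -7.413, CHAC1 0.852, STMN2 0.271, HES4 -1.446, FAS 0.479 and ALDH1A1 -7.801. Day 9 against day 6: E2F1 0.011, and 0.006 without both mixed libraries. Interaction of RA with CHIR99021 and BMP4: INHBA 14.474 and ALDH1A1 5.948. On log2(TPM + 1), without the covariate, DLX5 at -1.795 and HOXC4 at 0.874 reversed and passed (limma-trend adjusted p = 0.00192 and 0.0111). The Nodal and TGF-beta list at day 6 was lower by fry (adjusted p = 0.0044). The cause was not tested.

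Leaving out 1 library in turn gave 6621 to 7055 genes for RA at day 6, 9380 to 9868 for RA at day 9, 5586 to 6474 for CHIR99021 and BMP4, 5553 to 6407 for RA before these, 9145 to 9742 for these after RA, 6314 to 6947 for day 9 against day 6, 7637 to 8241 for RA by CHIR99021 and BMP4 and 7368 to 7886 for RA by day. Of 10905 refitted named-gene values, 317 lost and 220 gained the call.

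With the replicate number as a block, 7609, 10088, 6726, 6814, 10032, 7337, 8326 and 7931 genes were called in the same order. Same-numbered libraries correlated at -0.148 to 0.367, and in 0 of 15 group pairs were all 3 above 0.1. Every library correlated best with its own number for untreated day 6 with untreated day 9 (0.045 to 0.367). The same held for RA then CHIR99021 and BMP4 with day 9 RA (0.085 to 0.147) and with day 6 RA (0.049 to 0.063). In the other group pairs this was not so, and whether the numbers pair some libraries stays open. Under the block 37 named-gene values gained and 11 lost the call.

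Of 216 list values, 74 passed with the preset correlation and 0 of these with an estimated one, while 77 more passed by fry. On TPM values the median of all genes shifted by up to 0.322 in log2, so smaller changes depend on the scale. Totals differed 4.38-fold between libraries (5.79 to 25.37 M counts), so a gene at 1 CPM had about 5.79 counts in the smallest library.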

Other observations

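At day 9 after RA, NEFM, a neurofilament, rose from 0.915 ± 0.541 to 96.7 ± 2.05 CPM, TUBB3 from 3.35 ± 1.39 to 18.4 ± 4.53 CPM and MAP2 from 10 ± 2.56 to 42.3 ± 25.6 CPM, while their list of neural crest and neuron genes did not pass (4 rose and 1 fell of 11; camera adjusted p = 0.388, estimated 0.605). CGA, a hormone subunit of trophoblast, rose from 0.73 ± 0.274 to 46.3 ± 12.7 CPM, and ITGB6 from 3.53 ± 0.953 to 71.1 ± 15 CPM, with 5 of 10 amnion and trophoblast markers up and 3 down (camera adjusted p = 0.171, estimated 0.483). CGA was at 54 ± 13.5 CPM at day 6 after RA, and at 0.284 ± 0.113 CPM where CHIR99021 and BMP4 followed.

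ISG15 rose from 10.7 ± 3.27 to 42.2 ± 8.69 CPM at day 9 after RA, with 2 of 8 interferon genes up and 1 down (camera adjusted p = 0.347). Of the p53 genes 7 of 14 rose and 1 fell, with GDF15 up from 2.73 ± 2 to 19 ± 3.96 CPM and PLK2 from 123 ± 9.67 to 313 ± 49 CPM (camera adjusted p = 0.146). Where RA came before CHIR99021 and BMP4, SOX21 of the oesophageal list rose 34-fold (1.6 ± 0.539 to 51.8 ± 7.89 CPM) and TP63 fell 4.22-fold (48.3 ± 2.11 to 11.6 ± 0.939 CPM). GUCY1A2 was at 22.5 ± 7.51 CPM in untreated day 9 cells, 215 ± 35.1 CPM after RA and 356 ± 20.9 CPM after RA then CHIR99021 and BMP4.

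Some lists held members that went both ways, so that median and mean had opposite signs. The retinoid list at day 9 after RA had a median log2 fold change of 0.47 and a mean of -0.12, and the oesophageal list for RA before CHIR99021 and BMP4 -1.24 and 0.61. Pseudogenes held 19.16%, 25.13%, 19.11%, 11.22%, 9.87% and 15.88% of TPM in untreated day 6, untreated day 9, CHIR99021 and BMP4, day 6 RA, day 9 RA and RA then CHIR99021 and BMP4, against 2.88%, 4.02%, 2.61%, 1.61%, 1.34% and 2.2% of counts. Mitochondrial protein-coding genes held 5.68%, 6.73%, 5.29%, 5.04%, 4.18% and 5.59% of counts in that order, and ribosomal-protein genes 1.59%, 2.06%, 3.93%, 1.75%, 1.40% and 3.13%.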
